A study of Rattus norvegicus with 6 samples.

How the data were processed

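Total RNA from rat liver had been labelled with Cy3 and hybridised to NimbleGen arrays, per the labels' protocols, giving 1 profile for each of 6 samples. Samples were grouped by their titles into 3 given fermented dark tea and 3 given distilled water, both on the high-fat diet. The labels do not state that the replicates came from separate animals, so p-values measure the spread between these samples, which may in part be technical.

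The deposited value table holds 1 intensity per probe and array on a linear scale. RMA is named in the submitters' processing notes, and no version, background setting or probe-level value is given in the sources used here. RMA makes the intensity distributions of arrays alike and summarises several oligonucleotides into 1 value, so differences in total signal between samples are no longer visible. Beyond 1 random control row, the signal of the background is not given with the values. The design had allowed for values on a log or a linear scale. The values were found to be linear, so log2 was taken and no further scaling was applied. The table had 26420 rows. The 1 random control row was left out and 26419 probes were tested, of which 10113 carried identifiers of curated transcripts and 16306 those of predicted transcripts. No probe was left out for low signal.

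Probes were named by matching their transcript identifiers, without versions, to a reference table of the GRCr8 assembly, which was used for names only, and no coordinates are given. Of the probes, 9747 had 1 symbol, 0 had several and 16672 had none here. The named probes covered 9627 genes, 97 of them with several probes. For these the probe with the highest mean over the 6 arrays stood for the gene, and the mean of the probes was an alternative. Of the named genes, 1184 were olfactory receptors, a family of similar sequences whose probes may share signal.

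Tea was compared with control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over the 26419 probes and a threshold of 0.05. A screening count took probes at an unadjusted p under 0.05 and at least 1.5-fold. Standard errors and 95% intervals of log2 fold changes are limma's, and log2 fold changes are tea minus control. For 33 gene lists with at least 5 measured members, limma's camera was run with a preset correlation of 0.01 on 1 probe per gene, adjusted over the 33 lists, and repeated with an estimated correlation and with fry. The lists held 631 entries, with a gene on several lists counted each time, and 500 distinct genes among them were measured. They cover lipid, bile acid, glucose and drug metabolism, stress, inflammation, the circadian clock, growth hormone dependent genes, RNA quality and the cell types of liver. For each list, p-values were also adjusted over the list alone. Whole profiles were compared by the ratio of mean distances between and within groups, with an exact one-sided permutation test over the 10 splits of the 6 arrays. With 3 against 3 the smallest p of a permutation test is 0.1. Distances, correlations and principal components used log2 values of all probes.

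Named genes followed a rule. Per direction, 10 genes were taken: first those past the correction with non-overlapping groups, by size of change, then those at an unadjusted p under 0.01 with non-overlapping groups and a mean above the median of all probes. To these were added the 3 members of each list with the smallest p, given in the text for the lists described in most detail, and a fixed set that included Cyp7a1, Srebf1, Fasn, Scd, Cpt1a, Ppara, Cyp1a2 and Pck1. Srebf1 was not among the named probes. Some genes that the rule took are not reported here. The second step filled 9 of the places for higher genes and all 10 for lower genes. Groups, tests, gene lists, the rule and the alternatives below, except as stated, were set before the data were examined.

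The alternatives were quantile normalization once more, centring on array medians, a filter on dim probes, eBayes with trend and robust, array weights, the replicate number as a block, leaving out each array in turn, the mean of a gene's probes, Welch's test with Benjamini-Hochberg adjustment, an adjusted p under 0.1 and at least 2-fold. Testing named probes alone, leaving Dbp out of the clock list, and the estimated correlation with each array left out were chosen after seeing the data.

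The tests were tested on simulated data for dark tea against control with 26419 probes and the same spread in every array. Over 20 runs with 50 changed probes per fold size, 8.6% of 2-fold, 85.5% of 4-fold, 99.4% of 8-fold and 99.9% of 16-fold changes were recovered, and 7.12% of the calls were false. Each run held 200 changed probes at once, which eases the adjustment over all probes. The recovered shares therefore do not hold where few probes change or where 1 array stands apart, as in the real data. A shift of 1 on the log2 scale in the 24 cholesterol synthesis genes, simulated with 9627 genes, was called in 20 of 20 runs, with 0 calls among 640 tests of the other lists. The noise was drawn independently for each probe. The simulation therefore cannot show false list calls that arise where genes vary together. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.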

Results

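Gene expression was profiled in the liver of male Sprague Dawley rats on a 60% high-fat diet. The rats had been given either distilled water or a dark tea fermented with the fungus Eurotium cristatum, strain number 8730, and the tissue was taken at 9 weeks. There were 6 arrays, 3 from tea-treated rats and 3 from water-treated controls, each hybridised in a single colour to a rat expression array. The arrays carried 26419 probes, of which 9747 could be tied to 1 gene symbol each, covering 9627 genes. Median probe intensity lay between 87.1 and 95.9 over the 6 arrays. The number of arrays limits the precision of every value. All 6 arrays came from rats on the high-fat diet, and rats on a normal diet were not analysed here. The comparison asked how liver expression under the high-fat diet differed with the tea.

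The transcription factor Dbp, an output gene of the circadian clock whose liver transcript cycles strongly over the day, rose 19.5-fold in the tea group. Its log2 intensity was 10.25 ± 0.52 with tea and 5.97 ± 0.59 with water (SD, n = 3 each). The control mean lay below 6.47, the median of the mean levels of all probes, so the size of the fold is uncertain. The difference was 4.28 ± 0.39 on the log2 scale (SE, 95% confidence interval 3.41 to 5.16), and each of the 3 tea arrays lay above each of the 3 controls. Dbp was the 1 probe of 26419 that passed the correction for multiple tests (limma, adjusted p = 0.0142), and the next smallest adjusted p was 0.298. For Dbp alone, the exact two-sided permutation test over the 10 splits of the 6 arrays gave p = 0.1, the smallest it can give. The call was lost when tea replicate 1, 2 or 3 or control replicate 3 was left out, with limma adjusted p = 0.0554, 0.240, 0.193 and 0.0702, while the log2 difference stayed between 4.01 and 4.60 over all 6 omissions. With each probe's own variance in place of limma's pooled estimate, 0 probes passed. With 3 arrays per group, that test has little power for a lone probe of 26419, so this outcome says little about Dbp. With the replicate number as a block in limma, 0 probes passed as well.

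Among the 14 measured members of the circadian clock and output list, 8 had higher and 6 had lower mean levels with tea, with a median log2 fold change of 0.29. Adjusted over the list alone, 3 members were higher: Dbp, Per3 and Bhlhe41. Per3, a period gene, was higher by 1.22 ± 0.31 (SE), and Bhlhe41, a transcriptional repressor that acts on the clock, by 1.14 ± 0.30, both with limma adjusted p = 0.0138 over the list. Over all probes neither passed, with adjusted p = 0.949 for both, and both fell short over the list too when tea replicate 1 was left out. Further clock genes, chosen after their values were seen, did not pass over the list: Nr1d2 differed by 1.30 ± 0.47, Tef by 0.77 ± 0.31, Nfil3 by -1.28 ± 0.50 and Bmal1 by -1.95 ± 0.68. Nr1d2 differed by 0.73 without control replicate 1. It passed over the list without control replicate 3, and Nfil3 without control replicate 2. Bmal1, a core activator of the clock, had a log2 intensity of 7.04 ± 0.07 with tea (SD, n = 3), and of 7.03, 9.63 and 10.30 in control replicates 1, 2 and 3. Without control replicate 1 the Bmal1 difference was -2.92 ± 0.32 and passed over all probes (limma, adjusted p = 0.0018). Per2, also chosen after its values were seen, had a level of 8.58 in control replicate 1 against 5.75 and 5.93 in the other controls. The list as a whole did not pass limma's camera test across 33 lists (adjusted p = 0.0895, and 0.978 with an estimated correlation), though it did without tea replicate 1 or tea replicate 2, with adjusted p = 0.0374 and 0.0468. With an estimated correlation these adjusted p were 0.850 and 0.996, and the list's median turned to -0.031 without tea replicate 3. Without Dbp, an alternative chosen after seeing the data, its mean log2 fold change was 0.08 with an adjusted p of 0.459. Camera and the mean weigh higher against lower members, so opposite changes within the list cancel in both. By limma's fry, for change in either direction, the list with Dbp passed (adjusted p = 0.0021). That test was not run without Dbp.

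**Figure D1:**
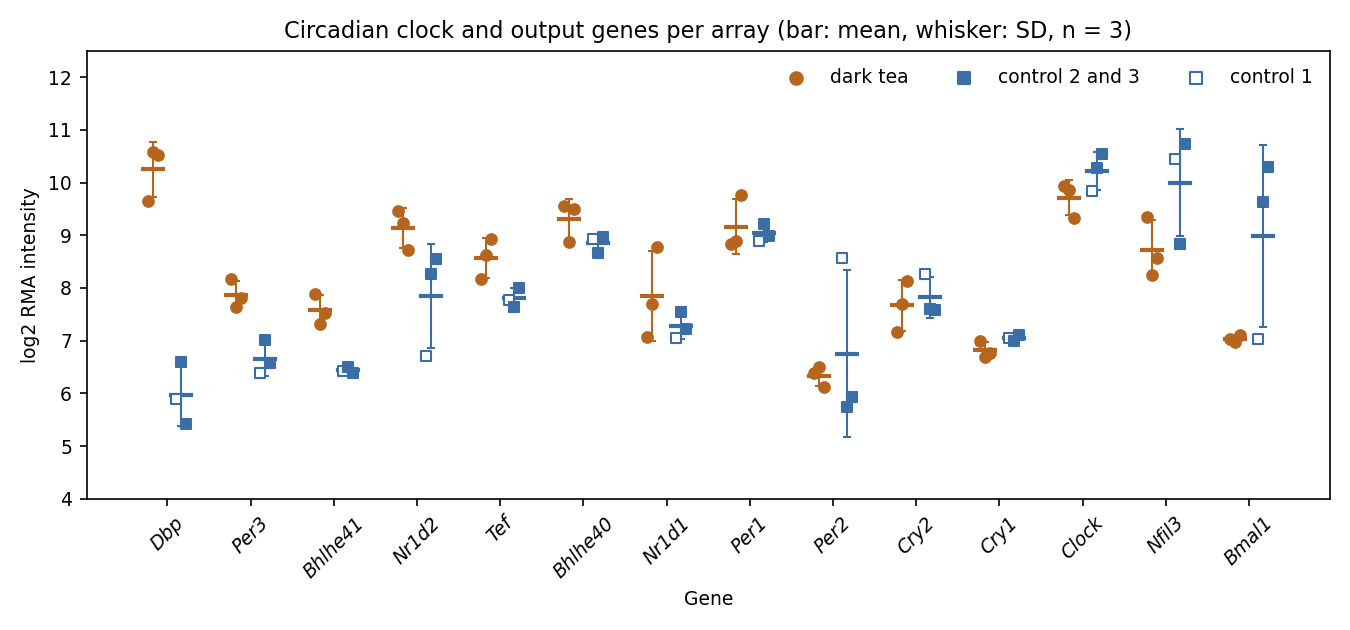
Log2 intensity (vertical axis) of the 14 measured circadian clock and output genes (horizontal axis) in each array. Circles are the tea arrays, squares the controls with replicate 1 open, bars the means and whiskers the SD of 3 arrays; Dbp lies near 10.25 with tea and near 5.97 in the controls, and Bmal1 in control replicate 1 lies at 7.03, beside the tea arrays.

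Control replicate 1 stood apart from the other 5 arrays. Its Pearson correlation over probes with each other array was 0.884 to 0.899, against 0.945 to 0.972 among the remaining 5. Principal component 1 held 50.5% of the variance and parted this array from the rest. Component 2 held 20.1%, with tea replicate 3 at -67.6 and the other arrays between -17.0 and 36.5. No separation of the groups over whole profiles was detected: the ratio of the mean distance between groups to that within groups was 1.003, with an exact one-sided permutation p of 0.6 over the 10 splits. Groups did not overlap for 2751 probes, 10.4% of all, where chance gives 10%.

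**Figure D2:**
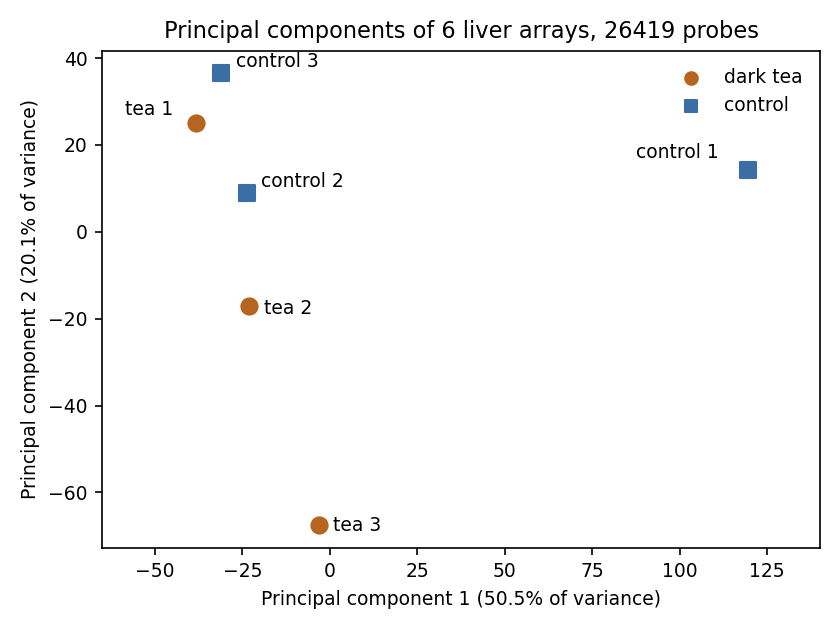
Principal component 1 (horizontal axis, 50.5% of the variance) against component 2 (vertical axis, 20.1%) of the 6 arrays over 26419 probes, with circles for tea and squares for controls. Control replicate 1 lies alone at the right, and the other 5 arrays lie at the left with no gap between the groups.

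Without control replicate 1, 6 probes passed the correction with limma, 2 higher and 4 lower with tea. The higher ones were Dbp and a probe with no gene name here. Bmal1 and Slc34a2 were among the lower ones. At an unadjusted p under 0.05, 1118 probes differed, 520 higher and 598 lower, each by at least 1.5-fold, where 1321 would be expected by chance. Without control replicate 1 this count was 1488, of which 611 were higher and 877 lower. It was 586 without tea replicate 2 and 713 without tea replicate 3.

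Apart from Dbp, the genes taken by size of change did not pass the correction over all probes with all 6 arrays, with adjusted p between 0.825 and 0.949, and their values are given as such. In each of these, the 3 tea arrays did not overlap the 3 controls, as the rule required. Higher with tea were Hsd17b2, which inactivates oestradiol and testosterone by oxidation, with a log2 fold change of 2.30 ± 0.46 (SE), and Sds, the serine dehydratase that feeds amino acid carbon into gluconeogenesis, with 1.75 ± 0.38. Por, the electron donor of the microsomal cytochromes P450, differed by 2.10 ± 0.64, and by 1.17 without control replicate 1. Cyth1 differed by 1.39 and by 0.90 without control replicate 1, Dcn and Npy by 1.33 and 1.30, and 3 olfactory receptor genes, Or2d3c, Or2a57 and Or4a66b, by 1.83, 1.44 and 1.38. Lower with tea was Chka, the choline kinase of phosphatidylcholine synthesis, at 5.50-fold and a log2 fold change of -2.46 ± 0.43. The phosphate transporter gene Slc34a2 differed by -1.76 ± 0.47 and by -2.34 without control replicate 1, where it passed over all probes (limma, adjusted p = 0.0213). The taurine transporter gene Slc6a6 and the amino acid transporter gene Slc1a4 differed by -1.58 ± 0.32 and -1.46 ± 0.30. Crot, a peroxisomal carnitine acyltransferase, differed by -1.54, Gckr by -1.45, Mpg by -1.42, G6pc1 by -1.42 and Inhba by -1.38. All 20 genes that the rule took by size of change, Dbp included, kept their direction without control replicate 1. The rule fixed this in advance, since groups that do not overlap cannot change direction when an array is left out.

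Glucose metabolism genes included members that moved in both directions. Of 20 measured members, 11 were higher and 9 lower with tea. Adjusted over the list alone with limma, Sds was higher with adjusted p = 0.0194, and 3 members were lower, among them G6pc1, the catalytic subunit of glucose-6-phosphatase, with adjusted p = 0.0476 and Ppp1r3c, a glycogen-targeting phosphatase subunit chosen after its values were seen, with adjusted p = 0.0489. None of the 4 passed over all probes. These calls rested on few arrays. None was left without tea replicate 2 or tea replicate 3. Sds was called in the other 4 omissions, G6pc1 without tea replicate 1 or control replicate 1, and Ppp1r3c without control replicate 3. Pck1, which commits carbon to gluconeogenesis, differed by -0.22 ± 0.33. The list as a whole had a median of 0.14 and a mean of -0.04, and camera gave an adjusted p of 0.922. The median was -0.24 without control replicate 1, and camera's direction turned from higher to lower.

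Of the lipid lists, 3 had an unadjusted camera p under 0.05, each with more members lower than higher with tea, and none passed across the 33 lists with all arrays. In the lipid droplet and storage list 7 of 10 members were lower, with a median log2 fold change of -0.25 and an adjusted p of 0.117. Plin2, a coat protein of lipid droplets, was 2.55-fold lower, with a log2 fold change of -1.35 ± 0.33 and limma adjusted p = 0.0223 over the list alone. It did not pass over all probes, with an adjusted p of 0.949. The list-alone value was 0.0843 without tea replicate 3, 0.0878 without control replicate 2 and 0.0753 without control replicate 3. G0s2, an inhibitor of triglyceride lipolysis, differed by -0.87 ± 0.37. In the list of fatty acid oxidation and PPAR-alpha targets 19 of 31 members were lower, with a median of -0.19 and an adjusted p of 0.117. Its leading members were the fatty acid hydroxylase genes Cyp4a2 and Cyp4a3, which differed by -1.20 ± 0.34 and -0.95 ± 0.31, and Angptl4, an inhibitor of lipoprotein lipase, which differed by -1.03 ± 0.38. Cpt1a and Ppara themselves differed by -0.02 ± 0.34 and 0.20 ± 0.45. Without control replicate 1, 27 of the 31 were lower, the list passed camera with an adjusted p of 0.000489, and 3 members passed over the list alone. The adjusted p was then 0.857 with an estimated correlation. The list also passed without tea replicate 1 (adjusted p = 0.0322, and 0.850 with an estimated correlation). Its mean log2 fold change went from -0.19 to -0.055 without tea replicate 3 and to -0.047 without control replicate 3, with adjusted p of 0.710 and 0.796, and its median turned to 0.0035 without tea replicate 3. In the fatty acid and triglyceride synthesis list 14 of 20 members were lower, with a median of -0.25 and an adjusted p of 0.117. Without tea replicate 1 both this list and the lipid droplet list passed, each with an adjusted p of 0.0374, and of 0.850 with an estimated correlation. The synthesis list had an adjusted p of 0.323 without tea replicate 2. The lipid droplet list had 0.502 without tea replicate 3, where its median was -0.051. Scd, the stearoyl-CoA desaturase, differed by -2.16 ± 0.83 and by -0.99 without control replicate 1. Fasn differed by 0.38 ± 0.30, from 0.23 to 0.53 with an array left out. Its log2 intensities of 5.14, 5.24 and 5.31 in the controls lay near the random control probe, so the size of this difference is uncertain. No member of the synthesis list or, with all arrays, of the oxidation list passed over its list alone.

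Genes that depend on growth hormone or sex in liver formed the list with the smallest camera p. The list was not split by the direction in which its members depend on growth hormone or sex. Its joint direction therefore does not tell whether growth hormone action or sex-dependent expression changed. Of 15 measured members 11 were lower with tea, with a median of -0.40, but the adjusted p was 0.0895, and 0.978 with an estimated correlation. Cyp4a2, shared with the oxidation list, led it, followed by Akr1c3 with -0.90 ± 0.37, and no member passed over the list alone. Akr1c3 had log2 intensities of 4.99, 5.78 and 5.55 in the tea arrays, with tea replicate 1 under its random control probe. The size of the Akr1c3 difference is therefore uncertain. Without control replicate 1 the list passed, with 13 members lower, an adjusted p of 0.000489, and 3 members past the threshold over the list alone. With an estimated correlation that adjusted p was 0.646. The list also passed without tea replicate 1 (adjusted p = 0.0374, and 0.850 with an estimated correlation). Without control replicate 3 its mean log2 fold change went from -0.39 to -0.25, with an adjusted p of 0.469.

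**Figure D3:**
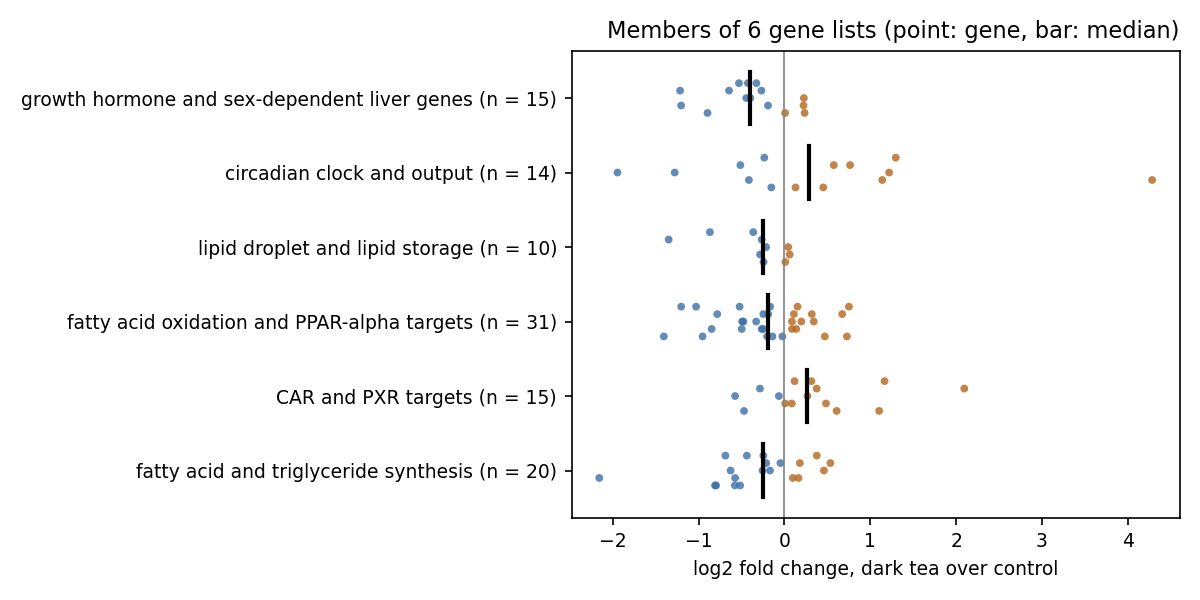
Log2 fold change of tea over control (horizontal axis) for each measured member of the 6 gene lists with an unadjusted camera p under 0.05 (rows). Points are genes and vertical bars medians, which run from -0.40 for the growth hormone list to 0.29 for the clock list; no list passed after adjustment with all 6 arrays.

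Drug metabolism genes under the receptors CAR and PXR were higher with tea in 11 of 15 members, with a median of 0.27 and a camera adjusted p of 0.117. The median was -0.05 without control replicate 1. After Por, the leading members were Gadd45b with 1.10 ± 0.42 and Ugt2b1, a glucuronosyltransferase gene, with 1.17 ± 0.46, or 0.74 without tea replicate 2. No member passed over the list alone with all arrays, and 2 did without control replicate 1. The aryl hydrocarbon receptor targets had a median of 0.05, from -0.067 to 0.075 with an array left out. Cyp1a2 differed by 0.53 ± 0.32, from 0.34 to 0.68 with an array left out. The NRF2 targets and antioxidant enzymes had a median of -0.15, which ran from -0.26 to 0.00020 with an array left out.

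Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had a mean log2 fold change of 1.38 ± 0.51, with tea arrays at 10.63, 9.71 and 8.32 against controls at 7.87, 8.09 and 8.54, so that the groups overlapped. The difference was 0.85 without tea replicate 1 and 2.002 without tea replicate 3. It did not pass over all probes (limma, adjusted p = 0.949) or over the bile acid list (adjusted p = 0.397). That list had 8 members higher and 10 lower, a median of -0.21 and a mean of 0.05. The cholesterol synthesis list had 11 members higher and 13 lower and a median of -0.025. It passed camera without tea replicate 1, with a median of -0.34 and adjusted p of 0.0322, and of 0.850 with an estimated correlation. Without tea replicate 3 its median turned to 0.28, with an adjusted p of 0.296. The lipoprotein and cholesterol efflux list had 13 of 18 members lower and a median of -0.10, which was -0.30 without control replicate 1 and 0.039 without control replicate 3.

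Markers of hepatocytes were balanced, with 8 of 16 higher, 8 lower and a median of 0.00043. Markers of periportal hepatocytes had a median of 0.27, from 0.15 to 0.41 with an array left out, and those of pericentral hepatocytes a median of -0.035, from -0.21 to 0.13. Of the pericentral markers 2 were lower over the list alone with limma, Slc1a4 with adjusted p = 0.0065 and the dicarboxylate transporter gene Slc13a3 with adjusted p = 0.0492, and the latter passed in 1 of the 6 omissions, that of control replicate 2. Neither passed over all probes. Medians for other cell types were 0.12 for Kupffer cells and macrophages, -0.021 for MHC class II presentation, 0.11 for lymphocytes, -0.30 for neutrophils, -0.079 for endothelium, 0.032 for stellate cells and myofibroblasts, 0.0049 for cholangiocytes, -0.065 for erythroid cells and platelets, -0.0052 for adipocytes and -0.11 for pancreatic acinar cells. With an array left out the neutrophil median ran from -0.41 to -0.095 and the endothelial median from -0.20 to 0.18. The median changed sign without control replicate 1 for the hepatocyte markers (-0.12), pericentral markers (0.13), Kupffer cells and macrophages (-0.23, with 10 of 13 lower), lymphocytes (-0.014), stellate cells (-0.027), erythroid cells and platelets (0.13) and adipocytes (0.13). Gzmb, the cytotoxic granule protease granzyme B, was the leading lymphocyte marker, with 1.29 ± 0.36 and limma adjusted p = 0.0759 over the list alone. The next markers by p, Prf1 and Gzma, went the other way, with -0.51 ± 0.29 and -0.49 ± 0.29.

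Inflammatory and acute phase genes had a median of -0.15, interferon response genes -0.028, fibrosis and extracellular matrix genes -0.25, unfolded protein response genes 0.076, cell cycle genes -0.14, immediate early and heat shock genes 0.20, oxidative phosphorylation genes -0.13 and cytosolic ribosomal protein genes -0.065. With an array left out these medians ran from -0.28 to 0.013 for inflammatory, -0.20 to 0.11 for interferon response, -0.23 to -0.074 for fibrosis, -0.18 to 0.35 for unfolded protein response, -0.26 to -0.012 for cell cycle, -0.0025 to 0.42 for immediate early, -0.22 to -0.045 for oxidative phosphorylation and -0.13 to 0.13 for ribosomal protein genes. No member of these lists passed over its list alone with all 6 arrays. Without control replicate 1 the interferon-induced gene Ifit1 and the matrix proteoglycan gene Dcn did, with log2 fold changes of -2.09 and 1.52 and limma adjusted p = 0.0078 and 0.0147 over their lists. Ifit1 had log2 intensities of 4.75, 5.33 and 5.83 in the tea arrays, with tea replicate 1 under its random control probe. The size of its difference is therefore uncertain. Of the 33 lists, 0 passed camera and 6 had an unadjusted p under 0.05, and the remaining 27 had adjusted p of 0.398 or more. With an estimated correlation 0 lists passed, with a smallest adjusted p of 0.978. By limma's fry, 0 passed for a change in one direction and 3 for change in either direction, the clock list, the fibrosis list and the pericentral markers. Without tea replicate 1, 7 lists passed camera, 2 higher and 5 lower, 2 passed without control replicate 1, and 1 without tea replicate 2. The 2 higher lists without tea replicate 1 were the clock list and the erythroid and platelet markers, with a median of 0.24 and an adjusted p of 0.0374 for the latter. With an estimated correlation, run for each omission after seeing the data, 0 lists passed in any of the 6, with a smallest adjusted p of 0.646. In 10 of the 33 lists the median changed sign without control replicate 1, in 23 it changed sign in at least 1 of the 6 omissions, and in all 33 it changed sign or moved by over 1.5 times in at least 1. The median, mean and camera direction differed in sign for 8 lists, namely bile acid, glucose, ribosomal protein, hepatocyte, MHC class II, stellate cell, erythroid and adipocyte genes, with a smallest unadjusted camera p of 0.275 among them.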

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

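Dbp was among the calls under a further quantile normalization, array centring, the dim-probe filter, eBayes with trend and robust, array weights and the mean of a gene's probes. The 1 called probe became 27 with array weights (9 higher, 18 lower), 0 with Welch's test and 0 to 6 with an array left out. The screening count of 1118 became 561 above the median level (fewer probes tested), 2998 with array weights, 520 with Welch's test, 418 at 2-fold (a stricter threshold), and 586 to 1567 with an array left out. The 0 lists became 1 with quantile normalization or array weights (growth hormone list, adjusted p 0.0479 and 0.0052), 1 with the dim-probe filter (fatty acid and triglyceride synthesis, 0.0150), and 0 to 7 with an array left out. The cause was not tested for those without one stated. The separation ratio ran from 0.918 to 1.14 with an array left out. Pck1 turned to 0.050 with array weights. With an array left out, Cpt1a ran from -0.25 to 0.16, Ppara from -0.29 to 0.57 and Pck1 from -0.42 to 0.015. Over 48 genes other than Dbp and 620 alternatives, 13 reached an adjusted p under 0.05 and 7 changed sign, in 3 genes. Testing named probes alone, chosen after seeing the data, left 1 call. Same-numbered arrays correlated at -0.22, 0.013 and -0.25 in their deviations from the group means. Tea replicates 1, 2 and 3 correlated best with controls 3, 3 and 1. Deviations from a mean of 3 arrays depend on each other, and control replicate 1 stood apart. The check therefore cannot decide whether the replicate numbers mark a batch or a day. With the replicate block 0 probes passed, with an adjusted p of 0.0932 for Dbp. Beyond 1 random control row, with intensities of 33.0 to 42.3 over the arrays, background signal is not given with the values. What dim probes could show is therefore largely unknown.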

Other observations

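The tests on control replicate 1 and of its part in the Dbp difference were chosen after the results were seen. The splits of the arrays and the further clock output genes were fixed as tests before those results were seen.

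Control replicate 1 differed from the mean of the other 5 arrays most at genes of several kinds. The protein phosphatase gene Ppm1a was 76.4-fold lower in it, Amacr, a racemase of bile acid and branched fatty acid metabolism, 42.6-fold, the actin-binding protein gene Cttn 33.7-fold, and the endoplasmic reticulum genes Dnajb9 and Sec11c 29.8-fold and 24.4-fold. Plscr3 was 22.4-fold higher, Lfng, a modifier of Notch receptors, 21.0-fold and Qsox1 16.1-fold. These genes were chosen after their values were seen. Against the other controls, 681 probes were at least 4-fold lower and 401 at least 4-fold higher, compared with 42 at least 4-fold apart between control replicates 2 and 3. The array also had the highest intensity of the random control probe, 42.3 against 33.0 to 35.6 on the others, the lowest SD of log2 intensity, 1.97, and the highest share of intensity in its 100 brightest probes, 23.1%. Its slope on the mean of the other controls was 0.829 on the log2 scale. The unfolded protein response list had a median of -1.07 on the log2 scale against the other controls.

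What set control replicate 1 apart stays open. A monotone distortion of its intensities would leave ranks in place, but its highest rank correlation with another array was 0.815, below the lowest of 0.902 among the other 5. A swap of labels with a tea array would make it resemble the tea arrays. Its highest Pearson correlation with a tea array was 0.897, below the lowest of 0.947 among the tea arrays. That outcome follows from its low correlation with every other array, the pattern to be explained. It is therefore no separate evidence on whether labels were swapped. Dilution by another cell type would lower hepatocyte transcripts in the sample. The hepatocyte markers had a median change of 0.0063 (SE 0.195), with an SD of 0.78 over the members. RMA makes the intensity distributions of arrays alike, so bright transcripts may keep their levels under dilution. The flat median therefore cannot exclude dilution. That SE is of a mean over the 16 marker genes of this 1 array, so it does not measure variation between arrays. RNA of a listed cell type as the source of the higher probes could not be decided, since the highest median rise of a marker list was 0.567, for cholangiocytes, between the bounds set for either outcome, and the labels give no difference between this rat or sample and the other controls that could be tested.

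Dbp, Per3 and Bhlhe41 lay higher with tea, with Bmal1 lower against control replicates 2 and 3. Control replicate 1 alone does not account for the Dbp difference, which was 4.25 without it (lower 95% limit 3.39). A candidate explanation is that the clock stood at another phase in the tea group when tissue was taken, whether through the hour of collection, feeding or the tea. The test was the mean log2 fold change of further clock output genes known to peak near Dbp, of which 7 were measured: it was 0.257, with 4 higher, at percentile 92.85 of 10000 random lists matched on level, and at percentile 76.76 without control replicate 1. The value with all arrays lies between the bounds set for either outcome. The one without control replicate 1 lies under both, in the range set for no phase difference. The test therefore does not decide on a phase difference. Since the tea could itself shift the phase, no outcome of this test could tell a phase difference from an effect of the tea on Dbp. The hour of collection is not given in the sources used here.

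With 10 splits of 6 arrays a share under 0.05 cannot be reached, so the splits are too few to decide on chance. The real split called 1 probe and the highest other 0, with 1 of 10 splits reaching the real count. For the screening count, 5 of 10 splits reached the real 1118. The highest other, which set control replicates 2 and 3 and tea replicate 1 against the rest, gave 2619, and its cause was not tested. For gene lists, 10 of 10 splits reached the real count of 0, which any split must reach, and the highest other was 8.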
